A study of Mus musculus with 18 samples.

How the data were processed

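RNA from adipose mesenchymal stem cells of FVB mice, cultured to within the fifth passage, was amplified and biotin-labelled with a linear amplification kit, per the labels, and hybridised to a custom mouse oligonucleotide array. The deposited raw sheet gives spot intensity, the pixel signal summed over the spot area, and a local background intensity beside each spot, per the file headers. The values are whole multiples of 257 in 2304 of 2304 cells. The sheets also give the authors' present or absent call and a bleeding (saturation) mark for each spot. A deposited report repeats the raw values (2088 of 2088 cells equal) without 12 spots, which leaves 10 genes to the raw sheet. The deposited series table holds, per the file headers and a check against the raw values, a ratio for 49 genes: the summed signal over the median of the housekeeping spots of the array, as the authors scaled it, to 2 decimals, with a largest difference of 0.010 from the recomputed ratio. The 18 columns each fit their own array best. The scanner and software version are not given in the sources used here. The sheets hold 23 arrays, and 5 of other samples are not used here.

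Each array has 128 spots: 117 for 64 genes (51 genes with 2 spots, 12 with 1 and 1 with 3), 4 blanks and 7 controls. All 64 symbols were matched to a reference gene table that names the assembly GRCm38.p6, 50 of them by accession. Spot intensity was divided by the spot area to give the mean pixel signal, since the area set for an array ran from 104 to 116 pixels and 17 spots on 4 arrays were under 95. Values were corrected with normexp (offset 50) in limma 3.58.1 (R 4.3.3), quantile normalised over the gene spots and averaged over the spots of a gene and over the arrays of a sample. A gene counted as detected in a sample where at least 50% of its spots were called present, and the 38 genes detected in at least 2 of 15 samples were tested.

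The design written before the data were examined used a local background column in normexp where there is one. That column follows the spots themselves: its mean beside Gapdh is 61369 against a Gapdh signal of 62843, and its use moves Gapdh from rank 2 to rank 38 of 64 genes and Ppia from rank 1 to rank 43. The values reported here therefore use the spot signal alone, a departure from that design. The choice was first made before any test was run, was then reversed, and was settled only after results under both had been seen. The design as written calls 1 gene at 6 months (Sbf1 is not called), 0 genes in each other comparison and 2 lists, PRC2 and the Trithorax methyltransferases, both at 6 months.

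Ages were compared with limma (lmFit and eBayes) in a fit with 5 age groups and 10 residual degrees of freedom: the F-test over ages, each older age against 1 month, and, in a second fit, the slope over log2 of age. P values were adjusted by Benjamini-Hochberg over the genes tested, at a threshold of 0.05. Of 14 gene lists fixed before the data were examined, 7 have a gene on the array and 5 have at least 3 tested members, and these were tested with fry, from limma, in 25 tests, adjusted over the lists of each comparison. Fry tests whether the members of a list move, on balance, one way, and does not compare the list with other genes. The lists without a member among the 64 genes, DNA methyltransferases, histone acetyltransferases, histone demethylases, histone kinases and ubiquitin enzymes, other SET domain methyltransferases, arginine methyltransferases and markers of other cell types, could not be tested. Genes of blood cells (Itgb2, Nckap1l and Ctsg), endothelium (Darc) and epithelium (Krt17), looked at after the data were seen, were detected in 0, 0, 0, 0 and 1 of 15 samples. The other single-spot genes outside the deposited report were also mostly undetected: Cxcl12, Ephb6, Prkg1 and Ptger3 in 0 samples each, against 9 for Fst. These calls therefore cannot tell absent cells from spots that give no signal. The lists of histone deacetylases and of other Polycomb partners have 2 tested members each and were not tested.

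The genes named were set by rule before the data were examined: genes past the threshold, a fixed list of 32 core genes (27 on the array), the 5 highest and 5 lowest in the trend and at 24 months, and genes detected in every sample of one age and in none of another. A part of these results is not reported here. Rbbp7 is named as a member of a fixed list, and Sirt1, Ncl and the calls within a set or between the sets were chosen after their values were seen.

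The 2 sets of arrays were read from the array names and their order in the sheets, and no label gives a date. Results are therefore also given with the set as a term and within each set. Alternatives planned before the data were examined were scaling on housekeeping genes, median centring, the authors' ratios, other background corrections, other filters, other treatments of technical replicates and of the replicate number, array weights (arrays that fit less well count less), a trend in the variance prior, fits with 2 ages only, other list tests and leaving out each of the 15 samples. Those added after the data were seen were the set of arrays, the design's background correction, summed intensity, an offset of 1000, subtraction of the plasmid control signal and leaving out the 2 dimmest samples. The pipeline was tested on simulated data with 38 genes, 10 of them changed. At 6 months against 1 month it recovered 65.1% of log2 changes of 1 and 90.7% of changes of 2, and at 24 months 57.0% and 86.8%. The changed genes were drawn from all 38, the 5 saturated ones included, although a rise in those could not be seen on real arrays. The noise was drawn independently for each gene, with no difference between sets of arrays. These shares may therefore overstate the recovery on the real data. With no change at all, 7 of 100 simulated data sets gave a call at 6 months.

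Array quality was compared over ages by permutation (100000 permutations of the F statistic). The raw median signal was 17620 ± 6500 (SD, n = 4) at 1 month and 10850 ± 2790 (n = 2) at 24 months, with a permutation p of 0.522. The permutation p was 0.908 for the share of genes detected and 0.0513 for the mean of the housekeeping genes. The second set of arrays, which holds both 24-month samples, is dimmer. Its median gene signals ran from 8286 to 18946, against 10099 to 33357 in the first set. Samples 1 and 8 of 1 month read 21700 and 33357 on the first set and 12813 and 18946 on the second. Over the 38 tested genes, arrays of the same sample differed by a median of 0.31 and 0.28 (log2) across sets and 0.32 within a set. These medians include the 5 saturated genes, which can hardly differ. The correlations of the paired arrays were 0.779 and 0.792 across sets and 0.874 within. Single genes differed by far more: Cbx7 by -4.506 and -2.003 across sets and by -1.934 within.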

Results

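Transcripts of Polycomb and Trithorax group genes, the chromatin regulators that keep genes silent or active through cell division, were measured in mesenchymal stem cells grown from inguinal fat of FVB mice. The donors were 1, 3, 6, 12 or 24 months old, with 4, 3, 3, 3 and 2 samples. A focused 1-colour oligonucleotide array of 64 genes was hybridised 18 times to these 15 samples, and 3 of the samples have 2 arrays. The median gene signal of an array lay between 8286 and 33357 pixel units, and 23 to 39 genes were called present per array. The number of arrays limits the precision. The arrays fall into 2 sets, with 11 samples on 12 arrays in the first and 6 samples on 6 arrays in the second. All 3-month and 6-month samples are in the first set and both 24-month samples in the second, while 2 of the 1-month samples have an array in each. Levels are given as mean normalised log2 signal ± SD over samples, and changes as log2 differences with the standard error (SE) from limma.

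Of the 64 genes, 38 were detected in at least 2 samples and tested, 20 were detected in all 15 samples, and 15 in none. Among the PRC2 genes, the complex that methylates lysine on histone H3, Eed and Rbbp7 were detected in every sample. The methyltransferase gene Ezh2 was detected in 1 of 15 samples, a 1-month one, while its paralogue Ezh1 was detected in 3 of 4, 3 of 3, 3 of 3, 2 of 3 and 0 of 2 samples from the youngest to the oldest age. Its detection follows the sets: a spot of Ezh1 was present on 12 of 12 arrays of the first set and 0 of 6 of the second. Among the PRC1 genes, Bmi1, Rnf2, Cbx2, Cbx7, Cbx8 and Phc2 were tested, and Ring1, Phc1, Phc3 and Pcgf2 were too dim. Mll1, Ash1l, Ash2l, Smarca2, Smarca4 and Hdac2 were tested, and Wdr5 was too dim. The housekeeping genes Gapdh, Rps27a, B2m, Hsp90ab1 and Ppia were saturated on all 18 arrays, so a change in them could not be seen. Cbx6, Dnmt1, Dnmt3a, Dnmt3b and Hdac1 were not analysed here.

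The first comparison asks whether any gene differs among the 5 ages. The genes with the lowest p were Sbf1, Rbbp4 and Fst, each at an adjusted p of 0.0666 in limma. Fst encodes follistatin, which binds activin. Fst has 1 spot on the array and is among the genes left out of the deposited report. Its levels were 13.68 ± 1.24 (SD, n = 4) at 1 month, 12.32 ± 0.36 (n = 3) at 3 months, 12.40 ± 0.68 (n = 3) at 6 months, 15.12 ± 0.46 (n = 3) at 12 months and 14.23 ± 0.43 (n = 2) at 24 months. It was detected in 0 of 3 samples at 3 months and in 3 of 3 at 12 months. Rbbp4, a histone-binding subunit of PRC2 and other complexes, stood at 13.12 ± 0.40 at 1 month and 13.51 ± 0.31 at 3 months, against 12.22 ± 0.20 at 6 months, 12.30 ± 0.17 at 12 months and 12.49 ± 0.75 at 24 months. It was detected in 3 of 4, 3 of 3, 2 of 3, 1 of 3 and 1 of 2 samples, so its levels at the 3 older ages lie near the detection limit. The limma F-test called 0 of 38 genes, and 13 had an unadjusted p under 0.05. With the set of arrays as a term it called 0, and within the first set alone it called 2, Fst and Rbbp4. The array weights described under processing raised the count to 9.

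**Figure D1:**
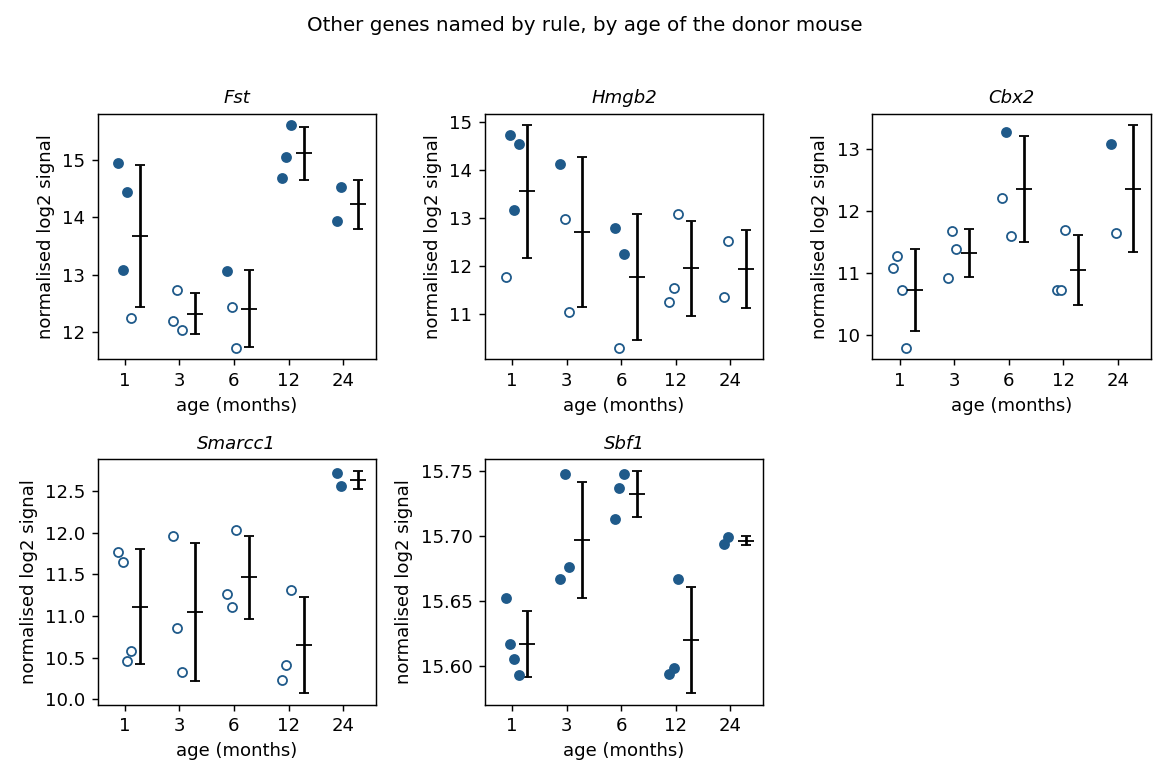
Normalised log2 signal of 5 genes (vertical axis) against the age of the donor mouse in months (horizontal axis). Each point is a sample, filled where the gene was detected and open where it was not, and the black bar is the mean ± SD. The 3 samples at 12 months average 15.12 for Fst, against 12.32 at 3 months.

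The second comparison asks for a steady change with age, as the slope over log2 of age in months. Hmgb2, an HMG-box protein that bends DNA, had a slope of -0.41 (SE 0.19) per doubling of age, and its mean ran from 13.55 ± 1.38 at 1 month (detected in 3 of 4) to 11.94 ± 0.82 at 24 months (detected in 0 of 2). Rbbp4, the PRC2 core gene Suz12 and the Polycomb partner L3mbtl2 had slopes of -0.22, -0.20 and -0.20, and Ezh1 -0.17. These 5 slopes were negative under every scaling of the arrays tried. The highest slopes were those of Cbx2, a chromodomain subunit of PRC1 detected in 2 of 15 samples, at 0.27, of Fst at 0.25, of the transcriptional repressor gene Bcl6 at 0.16, of the SWI/SNF subunit gene Smarcc1 at 0.16 and of the methyltransferase gene Mll3 at 0.11. The limma trend test called 0 of 38 genes, with 4 at an unadjusted p under 0.05 and a lowest adjusted p of 0.415. It called 0 with the set as a term and 0 within each set. The slopes of Cbx2, Bcl6, Smarcc1 and Mll3 turn negative with the authors' scaling, and within the first set that of Cbx2 is 0.03, that of Fst -0.08 and that of Smarcc1 -0.11.

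At 3 months against 1 month, the gene with the lowest level relative to the youngest donors was Fst, with a log2 difference of -1.36 (SE 0.59) and all 3 samples below the 1-month mean. With the undetected 3-month samples placed at the detection limit, the 1-month mean stood 1.35-fold higher, a log2 gap of 0.43. That is not a least fold, since the gap is smaller than the SE and Fst was detected in 3 of 4 samples at 1 month. Mll3 differed by -0.77 (SE 0.29) and Eed by -0.23 (SE 0.10), again with 3 of 3 samples lower. The PRC1 gene Bmi1 differed by -1.11 (SE 0.60) and Cbx7 by 1.11 (SE 0.59). None of these passed: limma called 0 genes, with 5 at an unadjusted p under 0.05 and a lowest adjusted p of 0.327. The count is 0 with the set as a term and 0 in the first set, where Fst differs by -2.02, Mll3 by -0.58, Eed by -0.09, Bmi1 by -0.54 and Cbx7 by 0.07, and the second set holds no 3-month sample.

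At 6 months against 1 month, the list of PRC2 genes fell. The mean over its 5 tested members went from 14.30 ± 0.17 (SD, n = 4) to 13.77 ± 0.06 (n = 3), a mean log2 difference of -0.53, and all 3 samples at 6 months lay below the lowest 1-month sample (14.07). Of the members, 4 were lower and 1 higher. The 2 that pass when adjusted over the list alone are the histone-binding genes Rbbp7 (-1.05, SE 0.34) and Rbbp4 (-0.90, SE 0.28; detected in 2 of 3 samples at 6 months), whose products also serve in other chromatin complexes. Both also moved together between the 2 arrays of a sample. Rbbp7 and Rbbp4 differed by -1.593 and -1.512 in sample 2 of 12 months, within a set. Across sets they differed by -1.127 and -0.916 in sample 1 of 1 month, and by -0.359 and -0.094 in sample 8. No 6-month sample has a second array, so the 2 genes cannot be read as independent falls. Suz12 differed by -0.88 (SE 0.44), Eed by -0.12 (SE 0.10) and Ezh1 by 0.32 (SE 0.54), none past its test. With the set as a term Ezh1 turns to -0.31 and Eed to 0.01, and within the first set Ezh1 is at -0.26 and Eed at 0.03, so the member that stands higher depends on the sets. In the test of the list with fry, from limma, p was 5.28e-04 and the adjusted p 0.00264 over 5 lists. Camera, a different test, asks whether the list moves more than the other tested genes. With an estimated correlation between members, its adjusted p is 0.0773. The mean is -0.65 with the set as a term, in a fit over the 18 arrays (adjusted p 0.00116 in limma). It is -0.66 within the first set (adjusted p 5.22e-04 in limma), and the second set holds no 6-month sample. The call ends when arrays are scaled on the housekeeping genes (-0.51, SE 0.46; adjusted p 0.43 in limma), centred on their median (-0.55, SE 0.23; 0.184) or taken as the authors scaled them (-0.42, SE 0.34; 0.695), against an SE of 0.13 here: the spread between samples is larger under each, and the mean is close to -0.53 under all but the last. It also ends with the local background subtracted and with the replicate number as a fixed block. The housekeeping genes, on which the authors' ratio also rests, are saturated, with means of 62211 to 63199 pixel units per array. The median gene signal ran from 8286 to 33357, so scaling on these genes corrects little of the brightness of the arrays. Median centring does not rest on them, and the call ends there too. The list passed in 22 of 28 alternatives.

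**Figure D2:**
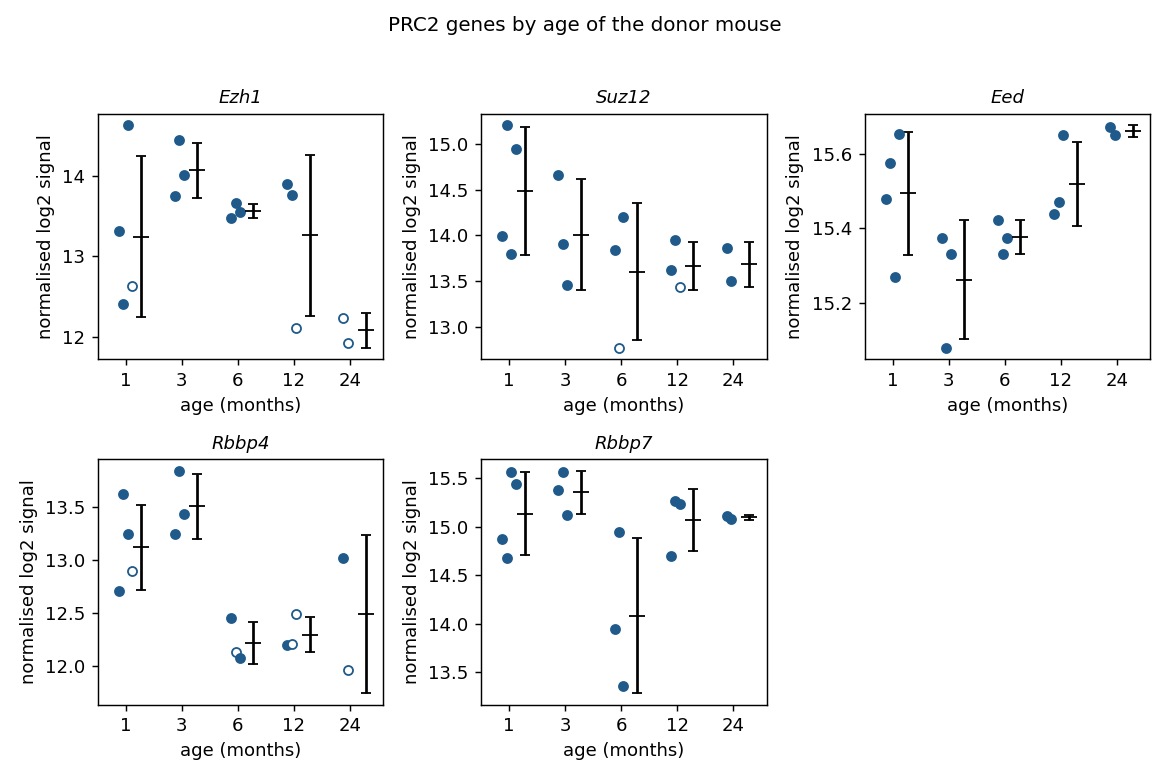
Normalised log2 signal of the 5 tested PRC2 genes (vertical axis) against the age of the donor mouse in months (horizontal axis). Each point is a sample, filled where the gene was detected and open where it was not, and the black bar is the mean ± SD. Rbbp4 averages 12.22 at 6 months against 13.12 at 1 month and Rbbp7 14.08 against 15.14, while Ezh1 averages 13.56 against 13.24, a difference that turns to -0.31 with the set of arrays as a term.

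Among single genes at 6 months, the PRC1 gene Cbx2 stood at 12.36 ± 0.85 (SD, n = 3; detected in 1) against 10.72 ± 0.66 at 1 month (n = 4; detected in 0). With so few detections no fold can be given for it, and its adjusted p in limma was 0.0833. Phc2 differed by 0.56 (SE 0.28), Fst by -1.28 (SE 0.59) and Hmgb2 by -1.77 (SE 0.96). With the set as a term these are 0.13, -1.62 and -1.01, and within the first set 0.23, -1.93 and -1.10. The gene that passed over all 38 was Sbf1, which encodes a relative of the myotubularin phosphatases and rose by 0.12 (SE 0.03; adjusted p 0.038 in limma; 3 of 3 samples above every 1-month sample). At 3, 12 and 24 months, 3 of 3, 1 of 3 and 2 of 2 samples also lay above every 1-month sample, so this is not particular to 6 months. The signal of Sbf1 was 57498 pixel units at 1 month and 60038 at 6 months, near the maximum of the arrays. All its spots were marked as bleeding on 2 of the 3 arrays at 6 months. In all, limma called 1 gene, with 6 at an unadjusted p under 0.05. The count is 0 with the set as a term (lowest adjusted p 0.0618) and 3 within the first set, Fst, Rbbp4 and Sbf1. With the deposited local background used in the correction, Sbf1 is no longer called and turns to -0.41 (adjusted p 0.327 in limma), and the count stays at 1. Sbf1 passed in 17 of 36 alternatives, and not with housekeeping scaling, median centring or the authors' values.

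At 12 months against 1 month, Fst was 1.44 higher (SE 0.59), with 3 of 3 samples above the 1-month mean and 2 above every 1-month sample, and the other way from its values at 3 and 6 months. Its single spot differed by 1.524 between the 2 arrays of sample 2 of 12 months, within a set. Across sets it differed by -0.211 and -0.844 in samples 1 and 8 of 1 month. Rbbp4 differed by -0.82 (SE 0.28), with 3 of 3 samples below every 1-month sample, and was detected in 1 of the 3. Suz12 differed by -0.82 (SE 0.44). Hmgb2 was detected in 0 of 3 samples, at a level of 11.95 ± 0.99, and no least fold can be given for it. Limma called 0 genes, with 2 at an unadjusted p under 0.05 and a lowest adjusted p of 0.489. The count is 0 with the set as a term. Fst differs by 0.54 within the first set and by 2.36 within the second, with 1 sample at 12 months, and Suz12 by -0.54 and -1.29. Within the first set, with 2 samples at 12 months, Rbbp4 is called (-1.16, adjusted p 0.0287), and within the second set, with 1 sample, Rnf2 is past the threshold (-2.12, adjusted p 0.0196 in limma). That value rests on a lone sample assumed to vary like the others, and over all samples Rnf2 differs by -0.51 (adjusted p 0.995 in limma).

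At 24 months against 1 month, no gene passed its test, and the values are those of the genes named by rule. The SWI/SNF subunit gene Smarcc1 was at 11.11 ± 0.69 at 1 month (SD, n = 4; detected in 0) and 12.64 ± 0.11 at 24 months (n = 2; detected in 2), with an adjusted p of 0.202 in limma. Smarcc2 was at 14.90 ± 0.25 and 15.48 ± 0.09, a difference of 0.58 (SE 0.21; adjusted p 0.202 in limma). In the fit with the set as a term, Smarcc1 was 0.595 higher in the second set (adjusted p 0.427 in limma). Over 33 alternatives its difference at 24 months ran from 0.107 to 1.856. Cbx2 was detected in 0 of 4 samples and 1 of 2, at 10.72 and 12.37. Bcl6 differed by 0.65 and Fst by 0.55, both turning negative when arrays are scaled on the housekeeping genes. L3mbtl2 differed by -0.92 (SE 0.39) and Suz12 by -0.80. Hmgb2, Ezh1, Arid1a and Ash2l, a core subunit of the histone H3 lysine methyltransferases of the MLL family, were detected in 0 of 2 samples at 24 months. Their levels there were 11.94, 12.08, 12.67 and 12.67, against 13.55, 13.24, 13.43 and 13.40 at 1 month. With the undetected samples placed at the detection limit, none of the 4 allows a least fold. Ezh1, Arid1a and Ash2l were detected in every sample of some younger age. Limma called 0 genes, with 6 at an unadjusted p under 0.05 and a lowest adjusted p of 0.202. Both samples lie in the second set: with the set as a term the count is 0, with 1 at an unadjusted p under 0.05, and the fitted difference of Ezh1 moves from -1.16 to -0.29, that of Arid1a from -0.76 to 0.15 and that of Smarcc2 to 0.33. Within the second set the count is 0, L3mbtl2 differs by -0.99 and the fitted difference of Ezh1 is -0.33.

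The remaining fixed lists gave no call with fry, from limma. The PRC2 list itself had adjusted p of 0.136 over the trend, 0.763 at 3 months, 0.122 at 12 months and 0.155 at 24 months, with means of -0.12, 0.14, -0.33 and -0.49. These comparisons share the 1-month samples and so their chance values. Among the alternatives, the PRC2 list passed in 3 of 29 over the trend, 0 of 28 at 3 months, 4 of 29 at 12 months and 2 of 28 at 24 months. The 7 PRC1 members averaged 0.38 at 6 months (adjusted p 0.25) and their median was -0.07. At 24 months their mean was 0.15 and their median -0.05. The 4 Trithorax methyltransferase members (Mll1, Mll3, Ash1l and Ash2l) averaged 0.18 at 6 months (adjusted p 0.238), with Mll1 at 0.32 (SE 0.16), and this list passes there with the set as a term (0.29, adjusted p 0.00109) and within the first set (0.35, adjusted p 0.00655). At 24 months their mean was -0.05 and their median 0.12. The 7 chromatin remodelling members averaged 0.26 at 6 months (adjusted p 0.25) and 0.22 at 24 months (adjusted p 0.175), and their mean and median differ in sign at 3 months (0.02 and -0.07) and 12 months (-0.06 and 0.01). This list passed in 1 of 29 alternatives at 6 months, 1 of 29 at 24 months and 1 of 30 over the trend. The 5 housekeeping genes, all at the ceiling, had a lowest adjusted p of 0.155, at 24 months.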

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

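The tests of the slope of Hmgb2 for a shared state of the cultures, and of the sets of arrays for the PRC2 list and for Ezh1 and Phc2, were chosen only after the result was seen, as were the fits with the set of arrays as a term. Phc2 at 1 month has a single low sample: sample 2 stands at 14.63 and the other samples between 15.19 and 15.25, a gap of 0.908 of the whole range. Sample 2 is the only 1-month sample measured in the second set of arrays alone, where Phc2 is lower by 0.78 over all samples (a difference of -0.78, adjusted p 0.00275 in limma). Of 40 such groups tested 1 stood out, and chance gives about 1 in 20. The plasmid control spots reach a mean of at most 6225 pixel units. Of the 4 blank spots, 1 is close to that at 6583 and 3 are far above it, at 14156, 25682 and 28426, and all 4 are called present on 0 arrays.

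The PRC2 list is lower at 6 months than at 1 month by 0.53 (a difference of -0.528, SE 0.125). A difference between the sets as the whole cause is excluded, since with the set as a term the difference is -0.645 (SE 0.155). The brightness of the arrays is excluded as the whole cause too, with -0.538 (SE 0.118) after a correction for the raw median. Of the 35 splits of the 7 samples 1, the real one, gives a list p as low (5.28e-04, against 0.0023 as the lowest of the others in fry). That makes chance unlikely for this list taken alone. It is the smallest share the design allows, for 1 of 25 list tests, so chance is not excluded. With housekeeping scaling the mean is about as large (-0.510) and the call ends because its SE grows to 0.455. Camera, which compares the list with the other tested genes, gives an adjusted p of 0.0773 with an estimated correlation between members. Age stays open as the biological explanation and was not tested apart from the culture.

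Hmgb2, Rbbp4, Suz12 and L3mbtl2, picked as the lowest slopes, together had a slope of -0.257 (SE 0.083) per doubling of age, which that choice makes larger in size, and Hmgb2 was detected in 6 of 15 samples and in 0 of 3 and 0 of 2 at 12 and 24 months. The slope of these 4 changed little with the set as a term (-0.265, SE 0.079) or with the raw median as a covariate (-0.238, SE 0.093). Ezh1, the next lowest, goes from -0.17 to -0.07 with the set as a term. The SEs take no account of the choice of genes by their slope in these same samples. The fits therefore show that the slope does not shrink much with either term, and not that a fall with age is real. Without Hmgb2 the slope of the other 3 is -0.207 (SE 0.061), -0.208 (SE 0.060) with the set as a term and -0.183 (SE 0.066) with the raw median. Whether these genes share a state of the culture, such as the share of dividing cells, cannot be decided: within ages, Hmgb2 and the mean of Ezh2, Suz12 and Rbbp4 have a Pearson r of 0.757 over the 15 samples (permutation p = 0.0148; Spearman rho = 0.682, permutation p = 0.0125; r = 0.613 without the 2 farthest samples and 0.901 over the 11 of the first set; 1 relation computed), but Ezh2 was detected in 1 sample and L3mbtl2 was not part of the test. No gene of the slope passed its own test, and age itself stays open and untested.

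Ezh1 and Phc2 are lower at 24 months than at 1 month in the fit over all samples, neither past its test. For Ezh1 a difference between the sets could account for the missing signal: a spot was present on 0 of 6 arrays of the second set against 12 of 12 of the first, and the 2 mice of 1 month with an array in each set had it on the first alone. For Phc2, detected in every sample, the difference is -0.615 (SE 0.331) over all samples and -0.368 (SE 0.247) within the second set. The same mice read lower on the second array, by -0.312 and -0.807. The sets and age cannot be told apart for Phc2, since the value within the second set is neither under 50% of the whole nor past 2 SE.

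In the comparison of 6 months with 1 month, 2 of 35 splits of the samples call as many genes as the real one (1, with 1 as the highest other), so chance cannot be excluded for Sbf1. At 3 and 12 months the real count is 0, so that 35 of 35 splits give as many by construction and the splits say nothing about chance (highest others 2 and 3).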

How the results depend on the processing

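The fits by set, with the set as a term, with the local background in normexp, on summed intensity, with another offset, with plasmid subtraction and without the 2 dimmest samples were chosen after the data were seen. The counts of 0 for the trend, 3 months and 24 months stayed 0 in every alternative run. The F-test count of 0 became 1 with median centring, 1 with genes detected in all 15 samples, 9 with array weights, 3 with a variance prior with a trend and 2 in the first set, and 0 to 2 leaving out 1 sample: 1 without sample 2 of 1 month, 2 without sample 3 of 12 months, and 1 without either sample of 24 months. The 12-month count became 1 in the first set and 1 in the second, the latter resting on a lone sample at 12 months. The 6-month count of 1 became 0 with housekeeping scaling, median centring, the authors' normalized values, local background subtracted, no filter, both arrays kept with the sample as a random block, only the 2 ages, the set as a term and summed intensity. It became 2 with no background correction, with the first array only and without the 2 dimmest samples, and 3 in the first set. Leaving out 1 sample gave 0 to 2: 0 without sample 8, 5 or 2 of 1 month, 5 of 3 months, 6 or 8 of 6 months or 7 of 12 months, 2 without either sample of 24 months, and 1 (Rbbp7, not Sbf1) without sample 7 of 6 months. Sbf1 at 6 months reversed to -0.464 with local background subtracted and to -0.407 with normexp on the local background, the correction the design names. The list count of 1 became 0 with housekeeping scaling, median centring, the authors' values, local background subtracted, genes detected in all 15 samples (which leaves too few PRC2 members to test) and camera with an estimated correlation. It became 3 with no filter, 2 with normexp on the local background, 2 with the set as a term and 3 in the first set. Leaving out 1 sample gave 1 to 7, with 7 without sample 1 of 1 month, and 4 and 2 without sample 1 or 2 of 24 months. The PRC2 mean at 6 months ran from -0.659 to -0.333 over 28 alternatives, with adjusted p from 2.83e-04 to 0.695, and passed in 22. No pairing of same-numbered samples was seen: the correlations of 12 pairs ran from -0.420 to 0.400 and 2 of 15 samples correlate best with their own number. Their mean was 0.035, against -0.005 for other pairs, and so few pairs cannot exclude a pairing. With the number as a fixed replicate block the 6-month count is 0 and the list count 0, and as a random replicate block they are 1 and 1. The median gene at 24 months shifts by 0.71 with median centring, -0.26 with housekeeping scaling and -0.52 with the authors' values, so differences at that age are relative to the scaling. At 12 months the shifts are 0.25, -0.20 and -0.30, and median centring moves 3 months by -0.17 and the slope by 0.13. Housekeeping scaling and the authors' values rest on saturated spots, so they correct little of the brightness of the arrays. Whether this makes their results differ was not tested, nor were other causes, beyond the fewer genes or samples of some settings. Signal over background limits the dim genes (26 of 64 not tested) and saturation the brightest.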

Other observations

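The fit with the set of arrays as a term was chosen after the data were seen. Over the 18 arrays, it shows 9 of 38 genes that differ between the sets in limma. Arid1a (-1.96, adjusted p 0.0027), Ezh1 (-1.51), Sirt1 (-1.40), Phc2 (-0.78) and Smarca2 (-0.46) are lower in the second set, and Ncl (0.59), Smarcc2 (0.53), Mll1 (0.36) and Eed (0.27) are higher. Sirt1, a histone and protein deacetylase, had levels of 14.80 ± 0.36 (SD, n = 3) at 3 months and 13.21 ± 0.34 (n = 2) at 24 months. Its difference from 1 month at 24 months is -0.76, and -0.06 with the set as a term.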
